A study of Americamysis bahia with 35 samples.

How the data were processed

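Whole-body RNA was sequenced from juvenile mysids (Americamysis bahia, a small estuarine crustacean used in toxicity testing) after 96 h in leachates of tire-wear particles, made with filtered seawater of 25 ppt. The labels put 35 libraries into 7 groups of 5. The groups were a control at 0 g/L, unweathered leachate at 0.27, 0.54 and 1.08 g/L, and weathered leachate at 0.67, 1.34 and 2.68 g/L. The labels do not say whether the 5 libraries of a group came from separate animals, pools or tanks, so p-values measure only the spread between these samples, which may be technical in part. Libraries were made from poly(A)-selected RNA with a directional kit, per the labels' protocols.

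The estimated count and the TPM, a length-scaled share of the library, of each of 34903 Trinity transcripts in each library were deposited by the authors, with transcript lengths beside them. Reads were trimmed with Trimmomatic 0.38 and quantified with kallisto, per the submitters' processing notes. Those notes also name DESeq2. The assembly the reads were assigned to and the version of kallisto are not given in the sources used here. A joined table of the authors' estimated counts held the same values, with 0 values more than 1% away from the single files. The authors also deposited a table for each of the 6 exposed groups against the control, with a log2 fold change, a fold change, a log2 mean expression (logCPM), a test score F, a p-value and an adjusted p-value (FDR) for 13326 transcripts, per the file headers. The headers carry the column names that edgeR's quasi-likelihood test writes. The transcripts of these tables held 98.1% of all counts, and 1896 transcripts at 1 CPM or more in every library lay outside them. How the 13326 transcripts were chosen is not given in the sources used here.

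kallisto divides reads among similar transcripts, so an estimated count of 1 isoform can move when another isoform of the same Trinity gene changes. The Trinity IDs group the 34903 transcripts into 22900 Trinity genes. The files used here do not pair IDs with gene names, and no reference was used, so transcripts are given by their IDs. For the same reason the gene lists on detoxification, stress, cuticle, tissue markers, energy and growth that had been fixed beforehand could not be run, and no list result is given.

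Everything that follows was computed here from the deposited estimated counts, rounded to whole numbers. Transcripts were kept by edgeR's filterByExpr with the groups (minimum count 10, minimum total 15), which left 27420 transcripts with between 99.86% and 99.96% of the counts of each library. Scaling used TMM factors. edgeR 4.0.16 in R 4.3.3 fitted a mean for each of the 7 groups to all 35 libraries, and the quasi-likelihood test compared each exposed group with the control and the 2 nearest pairs of concentrations of the 2 leachates. A second model had a common intercept and 1 slope per leachate in log2 expression per g/L, and tested each slope and their difference. Adjusted p-values are Benjamini-Hochberg values over the transcripts tested, and a transcript was called changed below 0.05. Standard errors of log2 changes were taken as the size of the log2 change divided by the square root of F. CPM values were computed from the counts and library sizes scaled by TMM.

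The design, the tests, the rule for naming transcripts and most alternatives were fixed before the data were examined. Since no names were at hand, the rule allowed at most 2 rising and 2 falling transcripts. It was applied as the largest rise and the largest fall at the highest concentration of each leachate, among transcripts with adjusted p under 0.05, a mean log2 CPM of at least 1 over the 35 libraries, and all 5 exposed libraries on the same side of the control mean. A transcript already named for the unweathered leachate was passed over for the weathered one.

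Total counts per library ran from 18081325 to 28390588. The fits were tested on simulated counts for 27420 transcripts drawn from the real means, dispersions and library sizes, with 200 transcripts changed. For unweathered 1.08 g/L against the control, 11.6% of 1.5-fold changes, 34.7% of 2-fold changes and 66.3% of 4-fold changes were called in the right direction, and 3.55% of calls were false. For weathered 2.68 g/L against the control the shares were 10.8%, 31.0% and 64.0%, with 1.75% false. A change of less than 2-fold was thus often missed with 5 libraries per group. For the unweathered slope 10.6% of calls were false and for the weathered slope 12.4%, above the 5% that the adjustment aims at. With nothing changed in 12 simulated sets, p-values under 1e-04 came 2.37 times as often as they should for the unweathered slope, 2.52 times for the weathered slope and 2.67 times for the slope difference. The same ratio lay between 0.547 and 0.942 for the group comparisons. Slopes were therefore also tested as linear contrasts of the 7 group means, for which the ratio was 0.638, 0.821 and 1.15. That alternative was added after this result was seen.

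Other alternatives were RLE size factors, no filter, a stricter filter (1 CPM in 5 libraries), DESeq2 1.42.0 and limma-voom with sample weights (limma 3.58.1). DESeq2 gave no adjusted p for up to 18079 of the 27420 transcripts in a comparison, so its adjustment covered fewer transcripts than edgeR's. Fits of the compared groups alone, the replicate number as a block and a minimum of 2-fold were also run. So were sums over Trinity genes and fits with each library left out in turn. The transcript set of the authors' tables, a fit without 2 libraries that stood apart, a robust estimate of the spread, upper quartile scaling and total count scaling were added after the data were seen. The overlap of the 2 leachates' calls was set beside lists of the same lengths, by smallest p, from simulated unchanged groups. In each simulated set both groups shared 1 control group, drawn anew like them from the means over all 35 libraries. This comparison was also added after the overlap was seen. Between-group differences in library measures were tested with two-sided permutation tests of a one-way F statistic with 100000 resamples. No column of per-sample values was left out. The response of respiration rate that the study also measured is not analysed here.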

Results

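The data were transcript counts from whole juvenile mysids exposed for 4 days to 1 of 2 tire-wear particle leachates, weathered or unweathered, each at 3 concentrations, beside a seawater control. Each of the 7 groups had 5 libraries. Mean total counts per library lay between 23355318 (SD 2513769, n = 5) at unweathered 0.54 g/L and 24495484 (SD 2660344, n = 5) at weathered 2.68 g/L, and did not differ between groups by more than the spread between libraries (permutation test, p = 0.991). From 28863 to 31069 of the 34903 transcripts had at least 1 count in a library. Correlations of log2 CPM between libraries ran from 0.835 to 0.927. The first 3 principal components, with 11.3%, 7.21% and 6.93% of the variance, did not separate the groups (permutation p = 0.678, 0.187 and 0.643). The fourth, with 3.96% of the variance, had 49.99% of its spread between groups against 17.6% by chance (permutation p = 0.00231). The fifth, with 3.87% of the variance, had 38.5% of its spread between groups (permutation p = 0.0205). The 5 components tested form 1 family, and these p-values are unadjusted.

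The comparison of unweathered leachate with the control asked which transcripts changed in abundance and at which concentration. At 1.08 g/L 303 transcripts were higher and 82 lower than in the control, of 27420 tested. The median change was 1.82-fold among those that rose and 1.66-fold among those that fell, and 147 changed at least 2-fold. Most called transcripts were abundant ones. Of the 385, 262 were among the 6855 most abundant tested transcripts and 14 among the 6855 least abundant. They belonged to 353 Trinity genes, of which 25 had more than 1 called transcript. In 0 of these 25 did called transcripts go in opposite directions.

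The largest rise by the fixed rule was that of TRINITY_DN734_c0_g1_i20, a transcript of 1915 bases. Its mean was 1.51 CPM (SD 0.506, n = 5) in the control, 11.1 CPM (SD 9.53, n = 5) at 0.27 g/L, 45.2 CPM (SD 38.9, n = 5) at 0.54 g/L and 114 CPM (SD 28.5, n = 5) at 1.08 g/L. The log2 change at 1.08 g/L was 6.24 (SE 0.892, edgeR adjusted p = 0.000134), and all 5 exposed libraries lay above the control mean, which the rule required. At 0.54 g/L it was 4.90 (SE 0.843, edgeR adjusted p = 0.0102), and at 0.27 g/L 2.88 (SE 0.782), which did not pass the test (edgeR adjusted p = 0.348). Summed over all transcripts of its Trinity gene, the log2 change at 1.08 g/L was 2.64, so the size of this rise holds for the isoform and not for the whole Trinity gene.

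The largest fall by the same rule was that of TRINITY_DN13160_c0_g1_i5, of 3178 bases. Over all calls at 1.08 g/L the log2 changes reached 7.435 and -8.07, in transcripts that the rule did not admit. Its mean fell from 193 CPM (SD 112, n = 5) in the control to 38.5 CPM (SD 26.0, n = 5) at 0.54 g/L and 28.6 CPM (SD 16.3, n = 5) at 1.08 g/L. The log2 change was -2.76 (SE 0.403, edgeR adjusted p = 0.000175) at 1.08 g/L and -2.33 (SE 0.396, edgeR adjusted p = 0.00987) at 0.54 g/L, where it was the only transcript called lower. At 0.27 g/L the mean was 89.6 CPM (SD 25.4, n = 5), and the log2 change of -1.11 (SE 0.381) did not pass the test (edgeR adjusted p = 0.592).

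**Figure D1:**
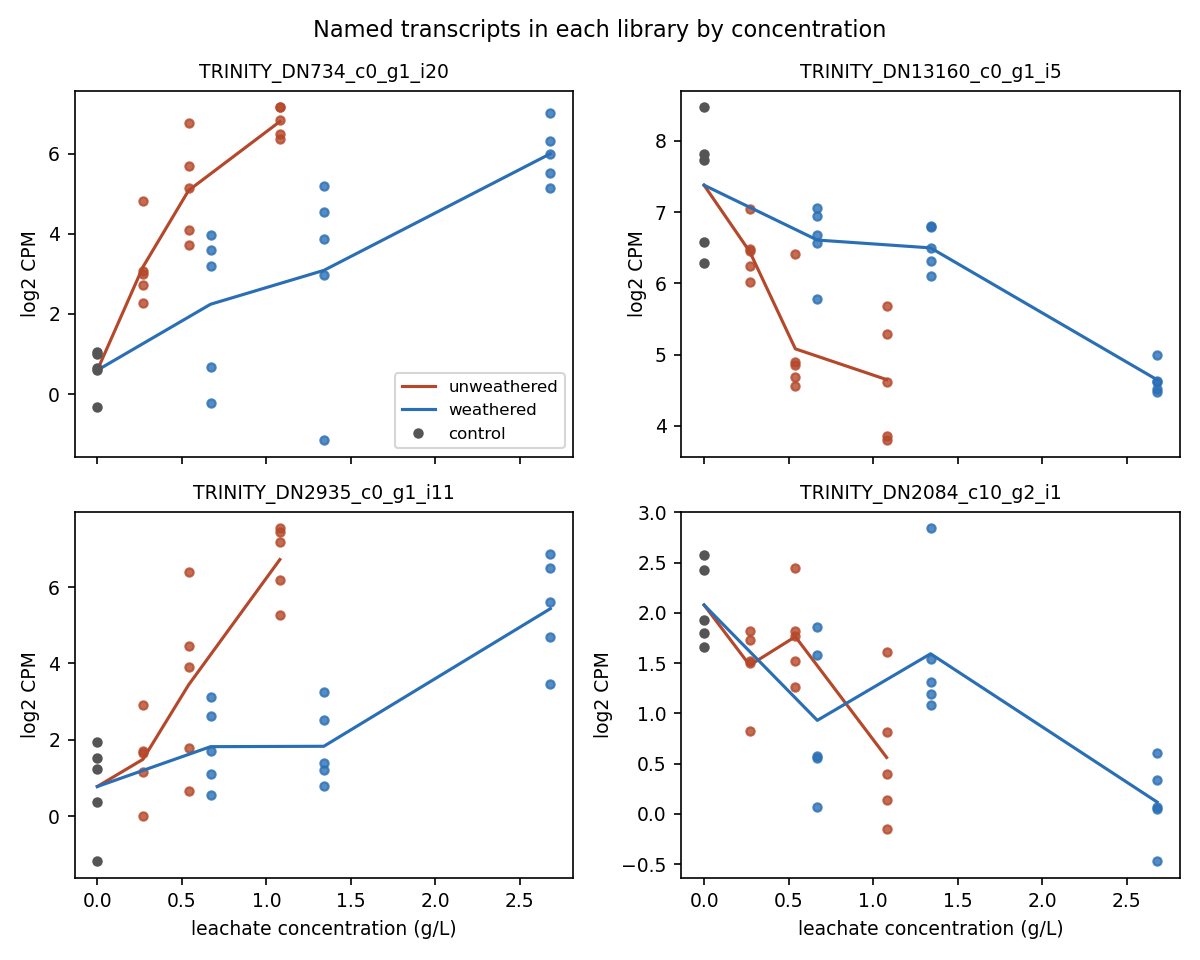
Log2 CPM of the 4 named transcripts (vertical axes) against leachate concentration in g/L (horizontal axes), with 1 point per library (5 per group) and lines through the group means, which start at the shared control. At unweathered 1.08 g/L all 5 libraries of TRINITY_DN734_c0_g1_i20 lie above the control mean, and those of TRINITY_DN13160_c0_g1_i5 lie below it, which the rule for naming them required.

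At 0.54 g/L 13 transcripts were higher and 1 lower, and 13 of these 14 were also called at 1.08 g/L in the same direction. At 0.27 g/L 2 transcripts were higher and 0 lower, and both were also called at 1.08 g/L in the same direction. These counts come from edgeR's quasi-likelihood test in 1 fit of all 35 libraries. With the compared groups fitted alone, 205 transcripts were called at 1.08 g/L, 0 at 0.54 g/L and 0 at 0.27 g/L. DESeq2 called 705, 133 and 71. Without replicate 3 of the 1.08 g/L group 235 transcripts were called at that concentration, and without control replicate 3, 250 were. At 0.54 g/L the count ran from 5 without control replicate 3 to 25 without control replicate 4, and at 0.27 g/L it was 0 in 5 of the 10 fits that left out 1 library. With upper quartile scaling, 246 of 368 calls at 1.08 g/L were rises (66.8%, against 78.7% with TMM).

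In the authors' deposited tables, 487 transcripts had an adjusted p under 0.05 at 1.08 g/L (335 higher, 152 lower), 26 at 0.54 g/L (24 higher, 2 lower) and 4 at 0.27 g/L (4 higher, 0 lower). Refitted on the 13326 transcripts of the authors' deposited tables, edgeR called 483, 26 and 4, of which 482, 26 and 4 were called in the deposited tables too. In the fit of 27420 transcripts, 50 of the 385 calls at 1.08 g/L lay outside the authors' deposited table.

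The comparison of weathered leachate with the control asked the same of leachate from weathered particles. At 2.68 g/L 100 transcripts were higher and 19 lower than in the control. The median change was 2.00-fold among those that rose and 2.55-fold among those that fell, and 63 changed at least 2-fold. Of the 119 called, 83 were among the 6855 most abundant tested transcripts.

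The largest rise and the largest fall at 2.68 g/L that the rule named beyond the 2 above were those of TRINITY_DN2935_c0_g1_i11 and TRINITY_DN2084_c10_g2_i1. The mean of TRINITY_DN2935_c0_g1_i11 was 2.08 CPM (SD 1.34, n = 5) in the control and 58.8 CPM (SD 44.4, n = 5) at 2.68 g/L, a log2 change of 4.79 (SE 0.892, edgeR adjusted p = 0.00506). It was higher at unweathered 1.08 g/L as well, at 123 CPM (SD 64.5, n = 5), with a log2 change of 5.86 (SE 0.935, edgeR adjusted p = 0.000458). At weathered 0.67 and 1.34 g/L its means were 4.27 and 4.30 CPM, and neither differed from the control by the test (edgeR adjusted p = 0.770 and 0.854). TRINITY_DN2084_c10_g2_i1 fell from 4.28 CPM (SD 1.24, n = 5) to 1.03 CPM (SD 0.298, n = 5), a log2 change of -2.04 (SE 0.387, edgeR adjusted p = 0.00597). It was lower at unweathered 1.08 g/L as well, at 1.54 CPM (SD 0.860, n = 5), with a log2 change of -1.47 (SE 0.379, edgeR adjusted p = 0.0407). At 17 to 30 counts per library at weathered 2.68 g/L, it was the least abundant of the 4.

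The transcripts named for unweathered leachate changed here too. TRINITY_DN734_c0_g1_i20 reached 70.8 CPM (SD 37.0, n = 5) at 2.68 g/L, a log2 change of 5.54 (SE 0.866, edgeR adjusted p = 0.000776). TRINITY_DN13160_c0_g1_i5 fell to 25.2 CPM (SD 3.85, n = 5), a log2 change of -2.94 (SE 0.406, edgeR adjusted p = 0.000225).

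At 1.34 g/L 3 transcripts were higher and 0 lower, and all 3 were also called at 2.68 g/L in the same direction. With the compared groups alone 0 were called at 1.34 g/L, and DESeq2 called 92 there, of which 41 were higher. At 0.67 g/L edgeR called 0, with a smallest adjusted p of 0.0568. There 2780 transcripts had an unadjusted p under 0.05, where chance gives 1371. DESeq2 called 344 at 0.67 g/L and limma-voom 18, while the authors' deposited table has 54 (17 higher, 37 lower). The count of 0 ended when any 1 library of the 0.67 g/L group was left out, with 8, 101, 3, 2 and 5 calls without replicates 1 to 5, and without control replicate 3, with 2 calls. Replicate 1 of weathered 0.67 g/L had the lowest TMM factor (0.775) and replicate 3 of weathered 1.34 g/L the lowest median correlation with the other libraries. Without both, 64 transcripts were called at 1.34 g/L (14 higher) and 6 at 0.67 g/L (0 higher). At 2.68 g/L the count was 62 without replicate 3 of that group, 67 without its replicate 5 and 79 without control replicate 5. It was 35 with the compared groups alone and 251 with DESeq2. The authors' deposited tables have 153 at 2.68 g/L (131 higher, 22 lower) and 12 at 1.34 g/L (10 higher, 2 lower).

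**Figure D2:**
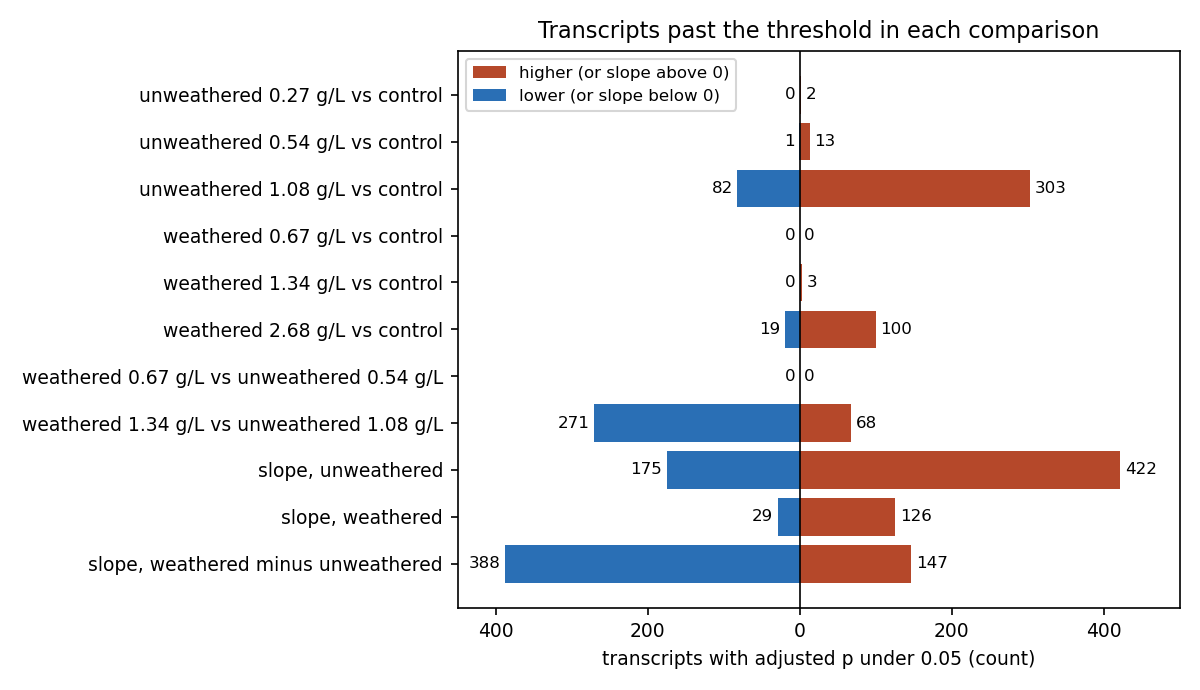
Number of transcripts with adjusted p under 0.05 (horizontal axis, a count) in each of the 11 comparisons, with those that rose or had a slope above 0 to the right of 0 and those that fell or had a slope below 0 to the left. The highest concentrations stand out among the comparisons with the control, with 303 and 82 transcripts for unweathered 1.08 g/L and 100 and 19 for weathered 2.68 g/L.

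The slope models asked which transcripts had a linear slope over the concentration of each leachate. Linearity was not tested, and a slope can rest on the highest concentration alone. The means of TRINITY_DN2935_c0_g1_i11 were 4.27, 4.30 and 58.8 CPM at weathered 0.67, 1.34 and 2.68 g/L. For unweathered leachate 422 transcripts had a slope above 0 and 175 below 0. For weathered leachate these were 126 and 29. Without replicate 3 of unweathered 1.08 g/L 386 unweathered slopes were called in place of 597, and without replicate 3 or 5 of weathered 2.68 g/L 92 or 97 weathered slopes in place of 155. With the compared groups alone the counts were 354 and 84, and with DESeq2 958 and 265. TRINITY_DN734_c0_g1_i20 rose by 5.33 log2 units per g/L (SE 0.670) of unweathered leachate and by 1.62 (SE 0.245) of weathered leachate, and TRINITY_DN2935_c0_g1_i11 by 5.97 (SE 0.630) and 1.78 (SE 0.232). TRINITY_DN13160_c0_g1_i5 had slopes of -2.62 (SE 0.349) and -0.93 (SE 0.152). The slope of TRINITY_DN2084_c10_g2_i1 was called for weathered leachate, at -0.67 (SE 0.151, edgeR adjusted p = 0.0220), and at -1.20 (SE 0.365) was not called for unweathered leachate (edgeR adjusted p = 0.0815). In simulation this model made more false calls than its threshold allows. As a linear contrast of the 7 group means, 391 transcripts were called for unweathered leachate, 347 of them among the 597 above, and 127 for weathered leachate, 108 of them among the 155. Upper quartile scaling gave 330 slopes above 0 and 295 below for unweathered leachate, so that the excess of rises over falls there depended on the scaling.

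The leachates were tested at different concentrations, so they were compared per g/L and between the nearest concentrations. The slope differed for 535 transcripts, with the weathered slope below the unweathered one for 388 and above it for 147. Above and below refer to signed slopes, so a weathered slope above the unweathered one can be a shallower fall. Such was TRINITY_DN13160_c0_g1_i5, with slopes of -2.62 for unweathered and -0.93 for weathered leachate. How many of the 147 were of this kind was not counted. Similar changes reached at different highest concentrations also give different slopes per g/L. For that transcript the log2 changes there were -2.76 (unweathered) and -2.94 (weathered). For TRINITY_DN734_c0_g1_i20 the weathered slope was lower by a difference of -3.71 (SE 0.541, edgeR adjusted p = 8.92e-05), and for TRINITY_DN2935_c0_g1_i11 by -4.18 (SE 0.509, edgeR adjusted p = 1.25e-05). For TRINITY_DN13160_c0_g1_i5, which fell, the difference was 1.69 (SE 0.304, edgeR adjusted p = 0.000890). For TRINITY_DN2084_c10_g2_i1 the difference of 0.53 (SE 0.312) did not pass the test (edgeR adjusted p = 0.468). As a contrast of the group means 124 transcripts were called in place of 535, and 120 of these were among the 535. Upper quartile scaling gave 264 above and 276 below. Without replicate 3, 4 or 5 of the unweathered 1.08 g/L group the count was 261, 321 or 298.

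Between weathered 1.34 g/L and unweathered 1.08 g/L, 68 transcripts were higher and 271 lower in the weathered group, although its concentration was the higher one. TRINITY_DN2935_c0_g1_i11 was lower there by a log2 change of -4.83 (SE 0.886, edgeR adjusted p = 0.00426), and TRINITY_DN13160_c0_g1_i5 was higher by 1.69 (SE 0.388, edgeR adjusted p = 0.0215). For TRINITY_DN734_c0_g1_i20 the log2 change of -2.80 (SE 0.748) did not pass the test (edgeR adjusted p = 0.0566). Upper quartile scaling gave 115 higher and 194 lower, and total count scaling 37 and 363. The count was 162 without replicate 3 and 196 without replicate 5 of unweathered 1.08 g/L, and 179, 224 and 183 without replicates 3, 4 and 5 of weathered 1.34 g/L. Between weathered 0.67 g/L and unweathered 0.54 g/L edgeR called 0 transcripts, with 2210 at an unadjusted p under 0.05 where chance gives 1371. DESeq2 called 151 there and limma-voom 0, and without replicate 3 of weathered 0.67 g/L edgeR called 13.

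The highest concentrations of the 2 leachates were compared to see whether the same transcripts changed. Of the 385 transcripts called for unweathered 1.08 g/L and the 119 for weathered 2.68 g/L, 97 were called in both, 85 higher and 12 lower, and 0 with opposite signs. Independent lists of those sizes would share 1.11 rises and 0.0568 falls. That leaves out that both comparisons used the same control libraries and that the calls of both lay mostly among abundant transcripts. In the simulated sets all libraries were drawn anew, and the 2 unchanged groups shared 1 simulated control group. These sets gave almost no calls, so their 385 and 119 transcripts with the smallest p were compared instead. Those lists shared a mean of 26.6 transcripts over 20 sets (16 to 36), against the 97 observed. Transcripts were simulated independently of each other, which real ones need not be. The simulated ranges given here can thus be too narrow. With the controls split into sets of 2 and 3 and each leachate set against a different set, in 20 fits, 7 to 23 transcripts were called in both (mean 15.4), with 0 of opposite sign. Fewer controls also shortened the lists. With 3 controls for unweathered and 2 for weathered leachate, means of 185 and 19.1 were called, and 11.9 in both. With 2 and 3 controls these were 72.4, 51.2 and 18.8. The shared counts are thus not comparable with the 97. The Pearson correlation of log2 changes over all 27420 transcripts, which are not independent replicates, was 0.524, where simulated unchanged groups gave a mean of 0.497 and at most 0.517. The covariance was 0.295, against a mean of 0.304 in the simulated groups, so it did not exceed theirs. The simulated value rests on the estimated spread put into the simulation, so it cannot show that an excess is absent. With disjoint controls the correlation had a mean of 0.118 and a range from -0.012 to 0.191. The covariance then had a mean of 0.112 and a range from -0.013 to 0.176. The log2 changes had the same sign for 70.2% of transcripts, against a mean of 66.7% and at most 67.4% in the simulated groups, and for a mean of 57.2% (50.9% to 61.9%) with disjoint controls.

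Transcripts called with 3 of the controls were then followed in the other groups against the remaining 2 controls, over all 10 splits. Those that rose at unweathered 1.08 g/L (111 to 214 transcripts) had a median log2 change of 0.30 at unweathered 0.27 g/L, 0.43 at 0.54 g/L and 0.87 at 1.08 g/L, and of 0.21, 0.23 and 0.59 at weathered 0.67, 1.34 and 2.68 g/L, as means over the splits. On average 95.8% of them were also higher at weathered 2.68 g/L. Those that fell at unweathered 1.08 g/L (21 to 61 transcripts) had a median log2 change of -0.13 at unweathered 0.27 g/L, with splits from -0.25 to 0.07, of -0.27 at 0.54 g/L and of -0.82 at 1.08 g/L. At weathered 2.68 g/L it was -0.40. At weathered 0.67 and 1.34 g/L it was -0.059 and -0.13, but its sign changed between splits, which ran from -0.30 to 0.11 and from -0.34 to 0.015. On average 90.4% of the falling set were also lower at weathered 2.68 g/L, and 54% at weathered 0.67 g/L, with splits from 34.4% to 76.9%. Those that rose at weathered 2.68 g/L (30 to 52 transcripts) had a median log2 change of 0.96 there and of 0.96 at unweathered 1.08 g/L. The value in the group that chose the transcripts is raised by that choice.

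**Figure D3:**
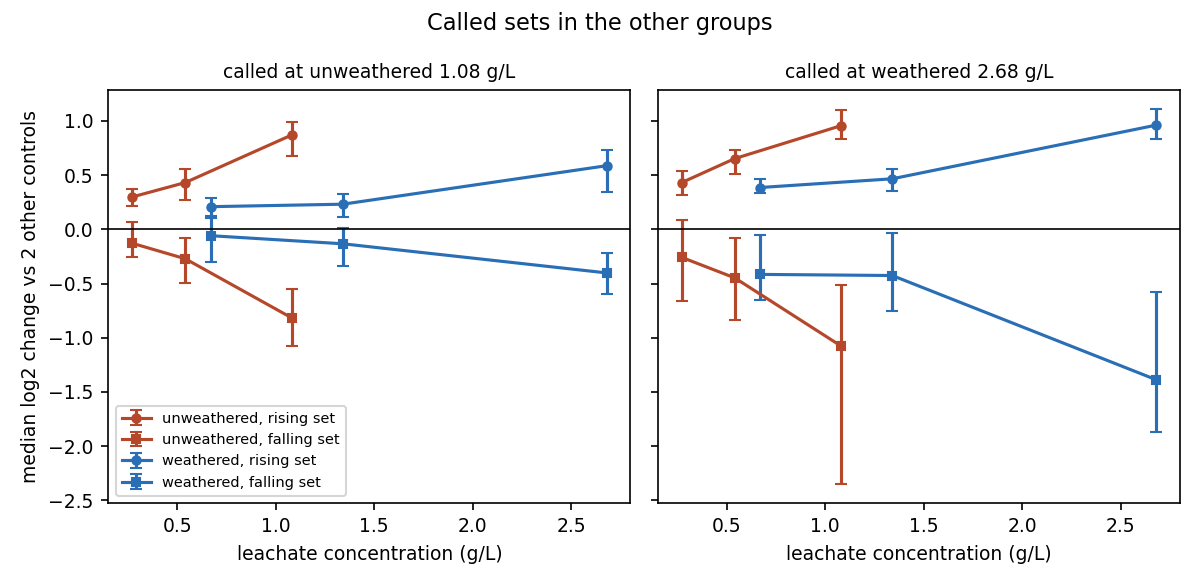
Median log2 change against the 2 controls not used to choose the transcripts (vertical axis) by leachate concentration in g/L (horizontal axis), for transcripts called at unweathered 1.08 g/L (left) and at weathered 2.68 g/L (right). Points are means over 10 splits of the controls and bars run from the lowest to the highest split. The rising set of unweathered 1.08 g/L has medians of 0.30, 0.43 and 0.87 over the unweathered concentrations.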

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

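Of the tests in this part, those of summing to Trinity genes, of the scaling, of the disjoint controls, of the covariance, of the calls made with no control library, and the splits of the libraries for every comparison with the control except weathered 0.67 g/L were chosen or had their reading fixed only after the result was seen.

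In 42 sets of 5 libraries examined for a library far from the others, 3 had one, where chance alone gives about 1 in 20. The TMM factor of control replicate 4 was 0.922, with the other controls between 1.08 and 1.13. The log2 CPM of TRINITY_DN13160_c0_g1_i5 was 6.41 in replicate 5 of unweathered 0.54 g/L, against 4.57 to 4.89 in the others. That of TRINITY_DN2084_c10_g2_i1 was 2.84 in replicate 3 of weathered 1.34 g/L, against 1.08 to 1.54 in the others.

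The slopes of the 2 leachates differed for 535 transcripts by the test of the difference itself, among them TRINITY_DN734_c0_g1_i20 (-3.71 log2 per g/L, weathered minus unweathered), TRINITY_DN2935_c0_g1_i11 (-4.18) and TRINITY_DN13160_c0_g1_i5 (1.69). Group labels were redrawn among the 35 libraries, and 1 of 100 draws, the real one, gave as many calls, with at most 1 call in the others. Such draws remove the effects of both leachates, so they bear only on no effect of either and do not test whether the 2 slopes were equal. The count depended on the model, with 124 calls as a contrast of the group means.

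The first pattern weighed is the number of calls at unweathered 1.08 g/L. With the 10 libraries compared fitted alone, 2 of 100 splits gave as many calls as the real one, which gave 205. The highest of the other splits gave 219, so libraries can part in another way with as large a result. The share of splits lay below 0.05, unadjusted for the other comparisons. It bears on the 205 calls of that fit and does not exclude chance for the 385. The first component of variation within the other groups, with its score as a covariate, left 374 of the 385 calls, with 512 called in all. That component held 13.4% of the variance within those groups. Its score did not differ between the control and unweathered 1.08 g/L by the test (exact permutation p = 0.111). This argues against that 1 component as the whole cause and does not bear on other components. Reads moved between isoforms are argued against for most of the calls, since 326 of the 353 Trinity genes were called after summing; among the 124 with more than 1 tested transcript this held for 97. Exposure to the leachate remains as a hypothesis, beside differences in tank or handling, which the labels do not give and which were not tested.

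The second pattern is that most calls at unweathered 1.08 g/L were rises. Falls hidden near the detection floor are argued against as the whole cause, since 72.9% of the 247 calls with a control mean of at least 10 CPM rose (exact 95% interval 66.9% to 78.3%). The interval treats transcripts as independent and does not measure the spread between libraries. The scaling moved the share but did not end it, with 66.8% rising as the lowest value under RLE, upper quartile and total count scaling. For the unweathered slope, in contrast, the share was 52.8% with upper quartile scaling.

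The third pattern is that the leachates share calls at their highest concentrations. Shared control libraries are argued against as the whole cause. With disjoint controls at least 7 transcripts were called in both in each of the 20 fits, where independent lists give 0.13 on average. The fits reuse the same libraries, so they are not 20 separate results. The number for independent lists leaves out that calls lay mostly among abundant transcripts. It also leaves out that both tests of a fit shared 1 estimate of the spread per transcript. They can account for part of it, since in simulated unchanged groups with the same controls lists of equal length shared a mean of 26.6 transcripts, against the 97 observed. Control libraries that stood apart from all exposed groups may also account for part of it: in the test fixed before its result was seen, the changes from the lowest to the highest concentration of each leachate, which share no library, correlated over all transcripts at 0.080, and 189 of 1000 relabellings were as high. The calls in the same comparisons, examined afterwards, argue against it for a few transcripts. There 7 were called in both in the same direction, where independent lists give 0.022. That number too leaves out the shared estimate of the spread. For the correlation over all transcripts, the covariance was -0.00863 relative to the simulated groups. The same-sign share was 70.2% against at most 67.4% in them. Their transcripts were drawn independently, so that range can be too narrow to decide. With disjoint controls the mean correlation was 0.118, with fits from -0.012 to 0.191. No control library is shared in those fits, so shared controls cannot give that mean. The fits reached below 0, and controls that stood apart from all exposed groups were not excluded there. For the correlation of 0.524 with all controls, a shared effect and the shared controls cannot be told apart.

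For weathered 2.68 g/L 1 of 100 splits, the real one, gave as many calls (35, highest other 2). For weathered 1.34 g/L against unweathered 1.08 g/L this was 1 of 100 (298, highest other 234). For the unweathered slope it was 1 of 100 (354, highest other 3) and for the weathered slope 1 of 100 (84, highest other 1). For these 4 the share of splits lay below 0.05, unadjusted, in the fits of the compared libraries alone. For weathered 0.67 g/L 9 of 100 splits gave as many calls as the real one, which gave 1 (highest other 41), and chance cannot be excluded. With the libraries compared fitted alone, unweathered 0.54 g/L (highest other 545), unweathered 0.27 g/L (highest other 116), weathered 1.34 g/L (highest other 33) and weathered 0.67 g/L against unweathered 0.54 g/L (highest other 2) gave 0 calls, so all 100 splits gave as many. For unweathered 0.54 and 0.27 g/L the splits with 545 and 116 calls were exceptions, since 12 of the other splits gave any call in each case. Whether they reflect a structure of the samples or calls that come together by chance was not tested.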

How the results depend on the processing

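The authors' transcript set, the fit without both libraries that stood apart, the robust spread, upper quartile and total count scaling and the linear contrast of the group means were chosen after the data were seen. Alternatives were run on the first 2 named transcripts at unweathered 1.08 g/L and on the other 2 at weathered 2.68 g/L only. Upper quartile and total count scaling were not examined for them, and TRINITY_DN2084_c10_g2_i1 was not in the authors' transcript set. In the alternatives examined, the direction and call of the named transcripts held, with log2 changes from 2.64 to 6.36 for TRINITY_DN734_c0_g1_i20, -3.08 to -2.42 for TRINITY_DN13160_c0_g1_i5, 4.37 to 5.11 for TRINITY_DN2935_c0_g1_i11 and -2.19 to -1.91 for TRINITY_DN2084_c10_g2_i1 and highest adjusted p-values of 0.00147, 0.0365, 0.0499 and 0.0295. The lowest value of the first came from summing to its Trinity gene. The calls of the first 2 at unweathered 0.54 g/L did not hold with only the groups compared, where 0 transcripts were called. The counts of calls below moved by over 1.5 times, and unless the setting itself changes what is tested the cause was not tested. In simulation at the real depth 34.7% of 2-fold changes were called at unweathered 1.08 g/L, so many changes of that size or smaller can be missing from these counts. The counts do hold smaller changes, since 147 of the 385 calls there were at least 2-fold.

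Against the control, from the highest to the lowest concentration, DESeq2 called 705, 133 and 71 transcripts for unweathered and 251, 92 and 344 for weathered leachate, and 873 and 151 for the nearest pairs (weathered 1.34 against unweathered 1.08 g/L and weathered 0.67 against unweathered 0.54 g/L). It called 958 and 265 slopes for unweathered and weathered leachate and 1043 slope differences. DESeq2 left up to 18079 of the 27420 transcripts without an adjusted p, so its counts differ from edgeR's in more than the test. limma-voom called 721 at unweathered 1.08 g/L, 32 at 0.54 g/L, 18 at weathered 0.67 g/L, 654 for the first nearest pair, 937 unweathered slopes and 856 slope differences. With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, 205, 0 and 0 were called for unweathered and 35, 0 and 1 for weathered leachate in that order, and 354 and 84 slopes. A minimum of 2-fold, which removes calls by its construction, left 147, 4 and 1 for unweathered leachate, 63 and 1 at weathered 2.68 and 1.34 g/L, and 101 for the first nearest pair.

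Sums over Trinity genes gave 28 at unweathered 0.54 g/L, 1 at 0.27 g/L, 6 at weathered 1.34 g/L, 62 at weathered 0.67 g/L, and 562 and 4 for the nearest pairs. The authors' transcript set gave 26, 4, 12 and 55 in those same groups, 567 and 10 for the nearest pairs and 826 slope differences. Without both libraries that stood apart the counts were 0 at unweathered 0.27 g/L, 64 at weathered 1.34 g/L and 6 at weathered 0.67 g/L. Without a filter 1 was called at unweathered 0.27 g/L. At weathered 0.67 g/L the stricter filter gave 26, RLE size factors 4, upper quartile scaling 13 and total count scaling 2. Total count scaling also gave 4 at unweathered 0.54 g/L, 0 at 0.27 g/L and 1 at weathered 1.34 g/L. As linear contrasts of the group means 391 unweathered slopes and 124 slope differences were called. The correlation of the 2 leachates' log2 changes was 0.118 with disjoint controls, where no control library is shared, against 0.524. Library totals did not differ between groups when only tested transcripts were summed (permutation p = 0.991).

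With each library left out in turn, the counts ran from 235 to 400 at unweathered 1.08 g/L, 5 to 25 at 0.54 g/L, 0 to 2 at 0.27 g/L, 62 to 142 at weathered 2.68 g/L, 2 to 6 at 1.34 g/L and 0 to 101 at 0.67 g/L. They ran from 162 to 314 for the first nearest pair and 0 to 13 for the second, from 386 to 649 for unweathered slopes, 92 to 201 for weathered slopes and 261 to 605 for slope differences. The lowest counts at unweathered 1.08 g/L, for unweathered slopes and for slope differences came without replicate 3 of unweathered 1.08 g/L, and the lowest at weathered 2.68 g/L and for weathered slopes without replicate 3 of weathered 2.68 g/L.

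Same-numbered libraries of different groups did not deviate together. The mean correlation of their deviations from the group means was 0.00276, against -0.000713 for different numbers, and ran from -0.212 to 0.306. Of the 35 libraries 9 were on average closest to their own number, where chance gives 7. With the replicate block 7 transcripts were called at unweathered 0.54 g/L and 1 at 0.27 g/L, in place of 14 and 2. The block moved no other count by over 1.5 times.

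The gene lists and their alternatives were not run, since the files used here do not pair the IDs with names. The slope difference was not fitted with only the groups compared, and a minimum of 2-fold was not set on slopes.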

Other observations

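A direct comparison of the highest concentrations, which was not planned, called 0 transcripts between weathered 2.68 g/L and unweathered 1.08 g/L with edgeR. At an unadjusted p under 0.05 there were 1854, where chance gives 1371. No other tool was run on this pair. The weathered concentration was the higher of the 2, and a count of 0 does not show that the groups were alike, since 31.0% of 2-fold changes were recovered in simulation for weathered 2.68 g/L against the control.

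Called transcripts were concentrated among abundant ones in both leachates. The recovery of changes was not simulated by abundance, so this need not mean that abundant transcripts changed more often. In 4 classes of 6855 tested transcripts, from the least to the most abundant, 14, 25, 84 and 262 were called at unweathered 1.08 g/L, and 5, 8, 23 and 83 at weathered 2.68 g/L.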
